A study of Mus musculus with 9 samples.

How the data were processed

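RNA was sequenced from C2C12 myotubes of 3 groups (vehicle, dexamethasone at 50 µM, and dexamethasone at 50 µM plus THSG at 10 µM, 24 h), with 3 libraries per group. Per the labels, RNA was extracted with a Hybrid-R kit and stranded mRNA libraries were prepared with a TruSeq kit. Sample titles all name the line C2C12, while the cell line field counts upward from sample to sample; the titles were followed. The submitters' processing notes name STAR 2.7.10a, featureCounts and the mouse build GRCm39 (mm39). The deposited table is described by its name as counts, but its values are fractional, carry 6 significant digits at most, and all exceed 1. The unit was therefore inferred, and the values were taken to be FPKM, that is, fragment counts scaled to transcript length and to library size. No header or label states this, and another scaled unit or further rescaling by the authors cannot be excluded. How counts were turned into these values, with which transcript lengths, which strand setting and which filter, is not stated in the sources used here. The table holds 10716 genes, each above 1 FPKM in all 9 libraries, so a filter on low values had been applied before deposition. Low values were not whole multiples of a common step, so reads could not be recovered and the depth of each library is unknown. The precision of each value is therefore known only from the spread between replicates.

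Each gene of the table carries an Ensembl identifier and a symbol. Of 10716 identifiers, 10670 were matched to GENCODE annotation of the mouse build GRCm38, and 46 were not. The annotation is of an earlier build than the authors used, so it served for symbols, transcript lengths and GC content, and no coordinates are given. Of the matched identifiers, 448 carried another symbol than the annotation. Among them, 50 symbols written in the style of human genes were replaced by the mouse symbol of the identifier, Postn among them. All other genes kept the symbol of the table. Lists and named genes were found by these symbols, so a gene listed under another symbol counts as absent.

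A count test had been planned before the data were examined. It needs counts, so the values were analysed as log2(FPKM + 0.1) with limma 3.58.1 in R 4.3.3. Gene-wise linear models with 1 mean per group were fitted to the 9 libraries together, and variances were moderated with an intensity trend. Each of the 3 comparisons was tested two-sided, with Benjamini-Hochberg adjustment over the 10716 genes and a threshold of 0.05. No further filter or scaling was applied. Confidence intervals are 95% intervals of the same models.

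Before the data were examined, 31 gene lists were fixed (pathways of muscle atrophy, growth, contraction, metabolism and stress, and markers of other cell types). The 28 lists with at least 5 genes in the table were tested with camera from limma, with a preset correlation between genes of 0.01 and adjustment over the 28 lists, and again with a correlation estimated from the data and with fry. With an estimated correlation, 7 of the 15 lists called for dexamethasone against vehicle kept their call, 0 of 5 for THSG against dexamethasone, and 7 of 15 for THSG plus dexamethasone against vehicle. That form of camera also rests on fewer degrees of freedom, so a lost call need not come from correlated members. For dexamethasone against vehicle, the inflammatory and myogenic lists lost their calls with estimated correlations of -0.015 and -0.01, below the preset. Fry tests whether the genes of a list move on balance in 1 direction, or in its mixed form in either direction, without comparison with other genes. List members were counted by the test over all genes, and adjusted over the list alone. The 3 lists not tested held 1 of 32 proteasome subunits, 4 of 16 heat shock and chaperone genes and 4 of 12 adipocyte markers.

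Genes named in the text were chosen by a rule fixed before the data were examined. It takes, for each comparison, the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean of at least 5 FPKM, a gene symbol and groups that do not overlap. It adds up to 4 genes per list with the smallest p, 14 genes fixed in advance, and genes with opposite calls. The rule was written for CPM values, and FPKM took their place. Names outside the rule are marked as such, and some genes that the rule gives are not reported here.

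Alternatives covered the pseudocount (0 and 1), median-ratio scaling, equal sums, quantile normalization, a minimum mean of 5 FPKM, no intensity trend, only the 2 groups compared, a replicate block, the removal of each library's trend over GC content and log2 transcript length (splines with 4 degrees of freedom), the replicate block with that correction, and leaving out each library in turn. To learn what sharing the dexamethasone or vehicle libraries does, 100 data sets with groups that did not differ were simulated, also with dexamethasone changes reduced by their noise variance and without dexamethasone replicate 3. In them, each library's deviations from its group mean were shuffled whole between libraries with random signs. Deviations of a group sum to 0, so some draws carry nearly no error and others a trend of a whole library. With THSG unchanged, genes at an unadjusted p under 0.05 ranged from 0 to 2017. The simulated ranges and shares are therefore rough guides and not exact chance levels. The tests were also tested on simulated changes added to 200 genes: for dexamethasone against vehicle, 23.9% of genes changed 1.2-fold, 80.6% of those changed 1.5-fold and 98.5% of those changed 2-fold were called, and 8.2% of the calls were unchanged genes (6.9% for THSG against dexamethasone). The simulated changes were set in noise that was independent between genes. Their rates need not hold for other numbers of changed genes or for trends shared within a library. Figures were drawn with matplotlib 3.10.9. Coordinates, splicing and single reads were not analysed here.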

Results

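Gene expression was measured by RNA sequencing in C2C12 myotubes, the multinucleated muscle cells that form when this mouse myoblast line is made to differentiate. The 9 libraries made up 3 groups of 3. Myotubes received vehicle, dexamethasone at 50 µM, or dexamethasone at 50 µM together with THSG at 10 µM, in each case for 24 h. Dexamethasone is a synthetic glucocorticoid used to bring about muscle wasting in culture. The labels give THSG only as an abbreviation, which in common use stands for tetrahydroxystilbene glucoside, a plant polyphenol. No group received THSG alone.

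The deposited table listed 10716 genes with values taken to be FPKM, and every value lay above 1 FPKM, so genes expressed below that level in any library were not analysed here. Why a gene is absent is not stated, and absence need not mean low expression. The table held only 1 of 32 proteasome subunits and 4 of 16 heat shock and chaperone genes. The 1 subunit, Psmd1, was listed under the symbol OCA2, and whether other absences follow gene symbols was not tested. Other lists were incomplete too, with 13 of 27 interferon response genes and 20 of 25 ER stress genes and ATF4 targets present. Of the genes fixed in advance, Tsc22d3, Klf15, Mstn, Igf1 and Ppargc1a were not found under these symbols. The values summed to between 400218 and 422379 FPKM per library, with medians from 12.1 to 12.8 FPKM. Read counts and sequencing depth were not given, so the counting error behind each value is unknown. Across genes, which are not independent replicates, log2 values of libraries within a group correlated with r between 0.991 and 0.994. The first principal component held 66% of the variance and placed the 3 vehicle libraries (-28.3 to -26.2) apart from the 6 libraries with dexamethasone (12.1 to 14.8). The second held 7.7%, with dexamethasone replicate 3 at -14.6 and the other 8 libraries between -4.5 and 7.3. Mitochondrially encoded genes took 14.0% of the summed FPKM in dexamethasone replicate 3 and 10.5% to 12% in the others. Values below are mean FPKM ± SD of 3 libraries, and fold changes are differences of log2(FPKM + 0.1).

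The comparison of dexamethasone with vehicle addressed how the glucocorticoid alone altered the myotube transcriptome. Dexamethasone raised glucocorticoid response genes, muscle atrophy ligases and genes of excitation-contraction coupling, and lowered genes of the cell cycle, cholesterol synthesis, the ATF4 stress response and the extracellular matrix. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose from 6.57 ± 0.21 to 97.8 ± 0.38 FPKM (n = 3 each), a log2 fold change of 3.88 (SE 0.044, limma adjusted p = 1.79e-13). Fbxo32, which encodes the muscle ubiquitin ligase atrogin-1, rose from 17.5 ± 0.72 to 74.3 ± 1.6 FPKM, a log2 fold change of 2.08 (SE 0.048, adjusted p = 4.8e-11). Of 10716 genes tested, 3601 (33.6%) changed at an adjusted p under 0.05, 1362 higher and 2239 lower, and 4664 had an unadjusted p under 0.05. Changes of at least 2-fold were found for 131 higher and 179 lower genes. In 45.9% of all genes the 3 libraries of each group did not overlap, where chance gives 10%. The balance of directions moved with the scaling between libraries, since 37.8% of the called genes were higher with values as deposited, 42.3% with libraries scaled to equal sums, 49.6% with median-ratio scaling and 50.5% with quantile normalization. Median-ratio and quantile scaling centre the typical change by design, so their even balance does not show that the excess of lower genes is an artefact. The labels do not say that replicates came from separate cultures, so all p-values given here measure only the spread between these libraries.

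Among the 8 genes with the largest rise were Ctla2a, a cysteine protease inhibitor, Mt2, a metallothionein, and Selenop, a secreted selenoprotein. Ctla2a went from 6.42 ± 1.1 to 861 ± 28 FPKM, a log2 fold change of 7.06 (SE 0.094). Its near-identical paralog Ctla2b was not analysed here. Mt2 rose from 123 ± 14 to 1774 ± 51 FPKM (log2 fold change 3.85) and Selenop from 32.5 ± 2.0 to 453 ± 15 FPKM (3.80). Ccdc152 rose by 3.94 on the log2 scale, and the annotation places its last exons on the opposite strand of Selenop; the strand setting used to count reads is not stated. The largest falls included Tnc, the matrix protein tenascin-C, from 41.5 ± 1.1 to 7.49 ± 0.72 FPKM (log2 fold change -2.46, SE 0.087), and G0s2, an inhibitor of adipose triglyceride lipase, from 33.0 ± 4.3 to 5.65 ± 1.3 FPKM (-2.55). Igfbp4, which binds insulin-like growth factors, fell by 2.50 on the log2 scale, Dynap by a log2 fold change of -2.39, and the collagen gene Col8a1 by one of -2.31. For each of these genes the 3 libraries of one group lay above the 3 of the other.

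Glucocorticoid response genes rose as a list. Of 24 measured members, 20 were higher and 1 was lower, both over all genes and adjusted over the list alone (camera adjusted p = 1.38e-21, and adjusted p = 0.00132 with an estimated correlation). Pdk4, a kinase that restrains pyruvate oxidation, rose from 7.41 ± 0.43 to 79.7 ± 2.6 FPKM (log2 fold change 3.41), and the kinase gene Sgk1 from 15.8 ± 0.87 to 100.3 ± 1.6 FPKM (2.66). Nr3c1, the glucocorticoid receptor gene, was the lower member, at 15.1 ± 1.1 and 11.5 ± 0.74 FPKM (log2 fold change -0.39, adjusted p = 0.00629). In the list of atrophy ubiquitin ligases and regulators, 11 of 23 members were higher and 1 was lower, and 12 and 1 when adjusted over the list alone (camera adjusted p = 6.42e-05, and adjusted p = 0.0225 with an estimated correlation). Trim63, which encodes the ligase MuRF1, rose from 20.3 ± 1.4 to 33.0 ± 2.9 FPKM (log2 fold change 0.69, SE 0.076). Cblb, another ubiquitin ligase gene, rose by 1.23 on the log2 scale. Mt1, which this list shares with the glucocorticoid list, rose by 2.67. Of the forkhead factors that drive atrophy genes, Foxo3 rose by 0.74, and Foxo1 was not called at 5.36 ± 0.28 and 4.66 ± 0.23 FPKM (log2 fold change -0.20, adjusted p = 0.108), although it passed after correction for GC content and length (-0.27).

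**Figure D1:**
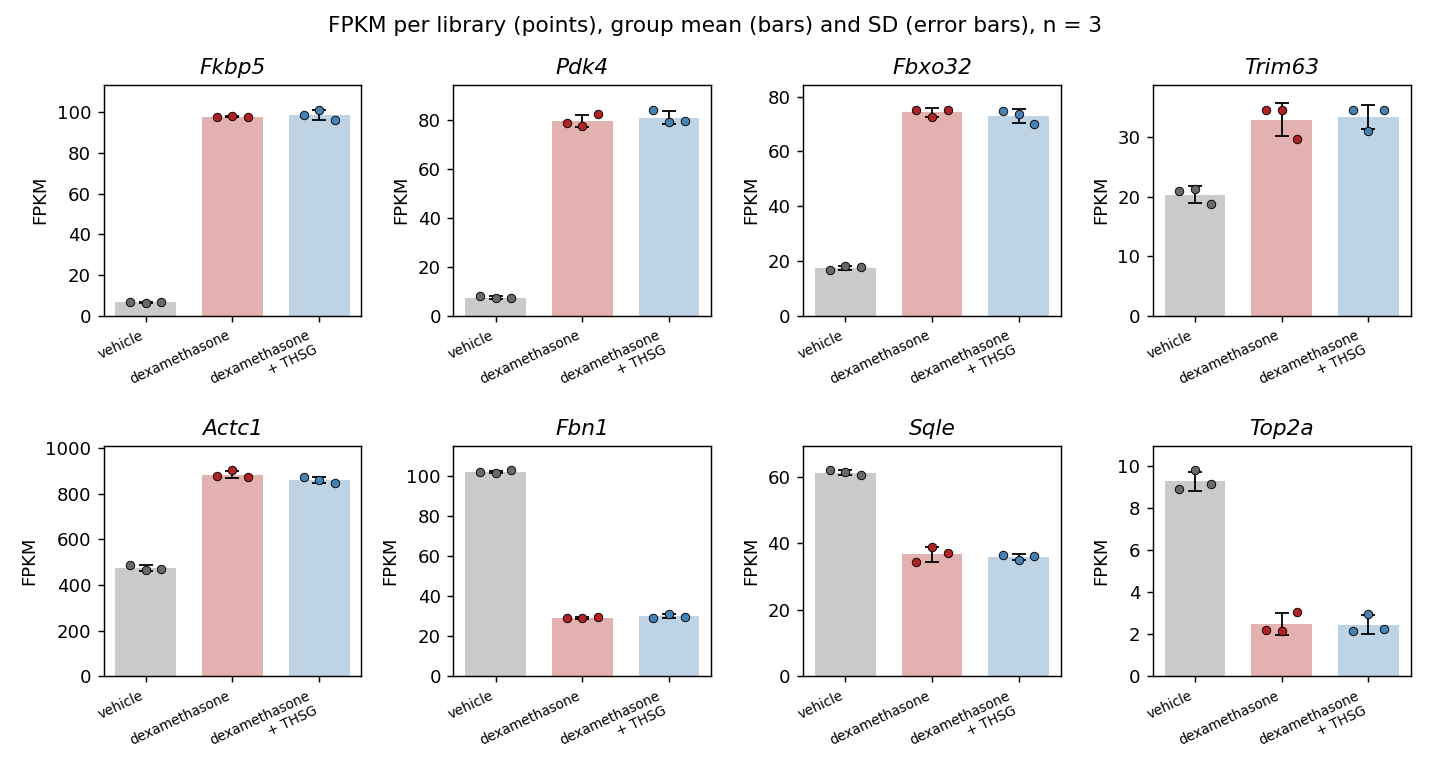
FPKM of 8 genes in each library (points), with group means (bars) and SD (error bars, n = 3), for vehicle, dexamethasone, and dexamethasone plus THSG; each vertical axis starts at 0. In every panel the 6 libraries with dexamethasone lie on one side of the 3 vehicle libraries.

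Genes of the muscle fibre machinery rose as well. In the sarcomere list 27 of 40 members were higher and 1 was lower, and 29 and 1 when adjusted over the list alone (camera adjusted p = 3.12e-14). That call was lost with an adjusted p = 0.0818 with an estimated correlation. Cardiac actin Actc1 rose from 475 ± 13 to 884 ± 17 FPKM (log2 fold change 0.90, SE 0.043), slow myosin Myh7 from 6.27 ± 0.30 to 20.1 ± 2.7 FPKM (1.66) and Myh1 from 277 ± 1.0 to 473 ± 27 FPKM (0.77). Ldb3, a Z-disc protein gene, rose by 0.52. Of 18 genes of excitation-contraction coupling and calcium handling, 15 were higher and 0 lower, and 16 were higher when adjusted over the list alone (camera adjusted p = 4.05e-10, and adjusted p = 0.0225 with an estimated correlation). The calcium pump gene Atp2a1 rose from 281 ± 7.5 to 433 ± 24 FPKM (log2 fold change 0.62), and the calsequestrin genes Casq1 and Casq2 by 0.38 and 0.44. Among 19 myogenic regulators and fusion genes, 7 were higher and 3 lower, and 10 and 4 when adjusted over the list alone (camera adjusted p = 0.0086, but adjusted p = 0.071 with an estimated correlation), and 1 was lower after correction for GC content and length. Six4, Ckm and the fusion gene Mymk rose by 0.84, 0.74 and 0.26. Myod1 was lower, at 79.8 ± 2.2 and 69.3 ± 0.99 FPKM (log2 fold change -0.20, adjusted p = 0.00324), a call that ended after correction for GC content and length (-0.10). Myog was 392 ± 12 FPKM with vehicle and 392 ± 7.4 with dexamethasone, a difference with a 95% interval from -0.10 to 0.10.

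Proliferation and sterol genes fell together. Of 20 cell cycle genes, 18 were lower and 1 was higher, with the same numbers adjusted over the list alone (camera adjusted p = 1.98e-08, and adjusted p = 0.0225 with an estimated correlation). Top2a, a topoisomerase of dividing cells, fell from 9.30 ± 0.45 to 2.47 ± 0.52 FPKM (log2 fold change -1.89, SE 0.156), and Cdc20, Ube2c and Ccnd1 had log2 fold changes of -1.67, -1.48 and -1.18. In the cholesterol synthesis list 19 of 20 members were lower and 1 was higher, again with the same numbers adjusted over the list alone (camera adjusted p = 9.2e-12, and adjusted p = 0.0437 with an estimated correlation). Sqle, squalene epoxidase, fell from 61.2 ± 0.77 to 36.7 ± 2.3 FPKM (log2 fold change -0.74, SE 0.051). Cyp51, a sterol demethylase, fell from 55.6 ± 1.6 to 33.1 ± 0.84 FPKM (-0.74, SE 0.044).

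Of 20 ER stress genes and ATF4 targets, 16 were lower and 1 was higher, and 17 and 1 when adjusted over the list alone (camera adjusted p = 2.86e-06, and adjusted p = 0.0339 with an estimated correlation). Trib3, a pseudokinase induced by ATF4, fell from 6.74 ± 0.46 to 1.78 ± 0.10 FPKM (log2 fold change -1.86), the asparagine synthetase gene Asns had a log2 fold change of -0.97 and the amino acid transporter gene Slc7a5 one of -0.66. The higher member was Vldlr, a lipoprotein receptor gene, at 5.60 ± 0.49 and 23.5 ± 0.89 FPKM (log2 fold change 2.06). All 27 measured extracellular matrix genes changed, 21 lower and 6 higher, with the same numbers adjusted over the list alone (camera adjusted p = 4.68e-06, and adjusted p = 0.043 with an estimated correlation); with median-ratio or quantile scaling 18 were lower. Fbn1, which encodes fibrillin-1, fell from 101.9 ± 0.70 to 29.1 ± 0.26 FPKM (log2 fold change -1.81, SE 0.043). The protease inhibitor genes Timp3 and Timp1 had log2 fold changes of -2.16 and -1.54. Periostin, Postn, rose from 48.5 ± 2.3 to 217 ± 6.6 FPKM (log2 fold change 2.16) and Ccn2, a target of TGF-beta, from 28.3 ± 0.86 to 104.7 ± 6.3 FPKM (1.88).

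Several smaller or weaker groups moved as well. Interferon response genes were lower in 9 of 13 cases and higher in 0, with the same numbers adjusted over the list alone (camera adjusted p = 0.00166, but adjusted p = 0.332 with an estimated correlation); Irf1 had a log2 fold change of -0.77. Of 16 inflammatory and NF-kB genes, 8 were lower and 2 higher, and 10 and 2 when adjusted over the list alone (camera adjusted p = 0.0147, but adjusted p = 0.0818 with an estimated correlation). The adhesion molecule gene Vcam1 fell from 31.7 ± 0.60 to 9.90 ± 0.52 FPKM (log2 fold change -1.67), and the cytokine genes Csf1 and Cxcl12 had log2 fold changes of -1.35 and -0.96. In the list of osteoblast and chondrocyte markers 4 of 5 members were lower and 0 higher, and 4 and 1 when adjusted over the list alone (camera adjusted p = 0.0123, but adjusted p = 0.183 with an estimated correlation). Osteopontin, Spp1, fell from 1760 ± 62 to 636 ± 23 FPKM (log2 fold change -1.47), and Bmp4 had a log2 fold change of -1.22.

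Of 16 genes of fatty acid oxidation and lipid storage, 5 were higher and 0 lower, with the same numbers adjusted over the list alone (camera adjusted p = 0.000974, but adjusted p = 0.168 with an estimated correlation). The list also holds Pdk4, already counted in the glucocorticoid list. The list's median log2 fold change was 0.09 and its mean 0.46. Lipoprotein lipase, Lpl, rose from 3.90 ± 0.42 to 17.3 ± 2.0 FPKM (log2 fold change 2.12), and the fatty acid transporter gene Cd36 rose by 1.11. Cytosolic ribosomal protein genes were lower in 14 of 32 cases and higher in 0, and 18 were lower when adjusted over the list alone (camera adjusted p = 0.00179, but adjusted p = 0.57 with an estimated correlation). Their number fell to 7 with median-ratio scaling, 9 with quantile normalization and 4 without dexamethasone replicate 3, and Rps23, at 354 ± 34 and 291 ± 14 FPKM, was among the 14. Of 13 mitochondrially encoded genes, 2 were higher and 0 lower, and 1 was higher when adjusted over the list alone (camera adjusted p = 0.0086, but adjusted p = 0.527 with an estimated correlation), while 4 were higher with median-ratio scaling. That list was also not called without dexamethasone replicate 3, the library with the largest mitochondrial share (adjusted p = 0.0846), or with quantile normalization (0.172). mt-Nd4 was 1574 ± 180 and 2041 ± 247 FPKM (log2 fold change 0.37, adjusted p = 0.00995).

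**Figure D2:**
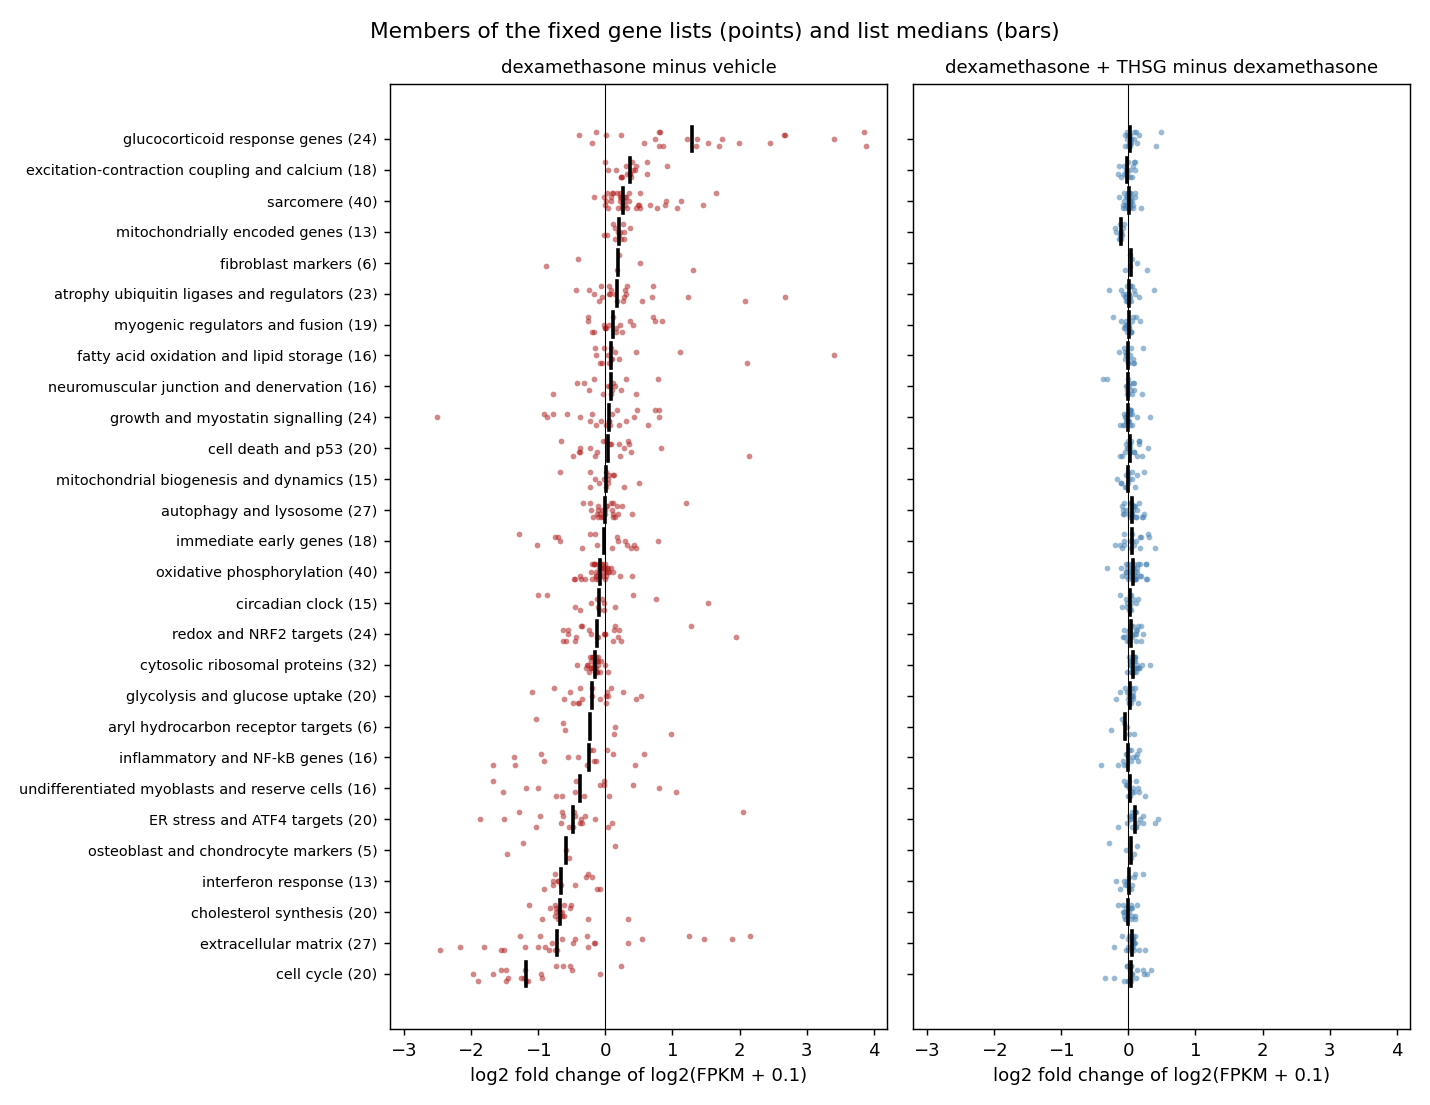
Log2 fold changes of the measured members of 28 fixed gene lists (points; number of members in parentheses) and list medians (black bars), for dexamethasone minus vehicle (left) and dexamethasone plus THSG minus dexamethasone (right), in order of the median in the left panel. Members reach 3.88 in the left panel, while medians in the right panel lie between -0.11 and 0.10.

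The comparison of dexamethasone plus THSG with dexamethasone alone addressed whether THSG altered the response to the glucocorticoid. No gene differed past the threshold between the groups, and the main targets of dexamethasone stood at similar levels with and without THSG. Fbxo32 was 72.9 ± 2.5 FPKM with THSG and 74.3 ± 1.6 without (n = 3 each), a log2 fold change of -0.03 with a 95% interval from -0.13 to 0.08. Trim63 was 33.4 ± 2.0 and 33.0 ± 2.9 FPKM (0.02, from -0.15 to 0.19), and Fkbp5 98.6 ± 2.7 and 97.8 ± 0.38 FPKM (0.01, from -0.09 to 0.11). For the receptor gene Nr3c1 the log2 fold change was 0.03 (from -0.17 to 0.23), for Myod1 0.04 (from -0.06 to 0.13), for Myog 0.02 (from -0.08 to 0.12) and for the deacetylase gene Sirt1 -0.11 (from -0.40 to 0.18). The limma test called 0 of 10716 genes, and the smallest adjusted p was 0.227. At an unadjusted p under 0.05 there were 777 genes (7.3%), 541 higher and 236 lower with THSG, but 434 and 311 with median-ratio scaling, 411 and 307 with equal sums and 388 and 352 with quantile normalization. In 13.3% of genes the libraries of the groups did not overlap, where chance gives 10%. Fold changes of all genes lay between -0.89 and 1.07 on the log2 scale, with a median 95% interval of 0.185 to either side.

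The genes nearest to the threshold among those named were Phlda3, a p53 target that restrains Akt, at 106 ± 3.5 FPKM with THSG and 87.0 ± 3.6 without (log2 fold change 0.29, and 0.16 after correction for GC content and length, adjusted p = 0.227), and the transcription factor gene Klf2, at 17.0 ± 0.52 and 13.7 ± 0.16 FPKM (0.31, and 0.20 after that correction, adjusted p = 0.23). Neither passed over all genes. Adjusted over the list alone, 2 immediate early genes passed, and 1 gene each of cell death and p53, glucocorticoid response, fibroblast markers and cytosolic ribosomal proteins, all higher. The immediate early list passed fry's mixed test, which asks whether members change in either direction (adjusted p = 0.00334), but not its directional test (0.307) or camera (0.241). Hmox1, heme oxygenase 1, a target of the antioxidant factor NRF2, was 22.8 ± 1.4 FPKM with THSG and 19.7 ± 0.67 without (log2 fold change 0.21, from 0.03 to 0.40, adjusted p = 0.676). Cebpd, of the glucocorticoid list, had a log2 fold change of 0.42 (adjusted p = 0.413).

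As lists, 5 of 28 passed camera with its preset correlation. The medians were 0.08 for cytosolic ribosomal proteins (adjusted p = 0.000172), 0.07 for oxidative phosphorylation and 0.10 for ER stress and ATF4 targets (adjusted p = 0.00476 each), 0.05 for the extracellular matrix (0.0346) and -0.11 for mitochondrially encoded genes (0.000952). All 5 were lost with an estimated correlation, with adjusted p = 0.847 for the ER stress list and adjusted p = 0.864 for the other 4 with an estimated correlation, and fry called 0 lists. All 5 were also lost without dexamethasone replicate 3, with adjusted p = 0.0607 for the ribosomal and the ER stress lists, 0.14 for oxidative phosphorylation, 0.0924 for the matrix and 0.287 for the mitochondrial genes. Oxidative phosphorylation was also lost without dexamethasone plus THSG replicate 1 (camera adjusted p = 0.558). The matrix list was also lost with median-ratio scaling, equal sums and quantile normalization (camera adjusted p = 0.0903, 0.145 and 0.479). It was lost too without an intensity trend, and on leaving out dexamethasone replicate 1, dexamethasone replicate 2 or dexamethasone plus THSG replicate 2. The medians of the 5 lists also shrank. Without dexamethasone replicate 3 they were 0.04, 0.03, 0.05, 0.04 and -0.04 in the order first given, and after correction for GC content and length 0.05, 0.04, 0.05, 0.04 and -0.06. With quantile normalization they were 0.02, 0.04, 0.08, 0.02 and -0.07. Across all genes, which are not independent replicates, the change with THSG correlated with GC content (Spearman rho 0.39, and 0.22 without dexamethasone replicate 3). For dexamethasone against vehicle rho was -0.2 (-0.13 without that library), and for dexamethasone plus THSG against vehicle -0.04. No member of the 5 lists passed over all genes, and adjusted over the list alone the ribosomal gene already counted did. Members with the smallest p included Rpl13, at 515 ± 20 FPKM with THSG and 413 ± 27 without, Sdhc (58.1 ± 6.6 and 48.1 ± 1.1), Uqcrc1 (67.1 ± 2.2 and 58.9 ± 4.6), Phgdh (29.0 ± 1.2 and 24.8 ± 1.6), Ddit3 (22.7 ± 1.4 and 19.5 ± 1.4), Atf5 (30.7 ± 1.5 and 23.1 ± 6.1), Timp1 (97.7 ± 2.7 and 87.6 ± 2.8) and mt-Nd4 (1775 ± 43 and 2041 ± 247). Without dexamethasone replicate 3 the log2 fold change of Atf5 went from 0.44 to 0.24 and that of mt-Nd4 from -0.20 to -0.10, and across all settings that of Sdhc, 0.27, was 0.18 at the lowest.

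No gene passed in opposite directions in the comparisons of dexamethasone with vehicle and of THSG with dexamethasone. These share the 3 dexamethasone libraries, whose errors alone make changes look reversed. Among genes called with dexamethasone, 357 moved in the opposite direction with THSG at an unadjusted limma p under 0.05. The mean was 206 (range 0 to 1195) in 100 simulations of a THSG group that did not differ from dexamethasone. These simulations reuse the deviations of the measured libraries, so their ranges are a rough guide only. In the same direction 55 moved, against a simulated mean of 75 (range 0 to 377). The correlation across genes between the dexamethasone change and the THSG change was -0.25, within the simulated range of -0.38 to 0.20 (mean -0.14). Their covariance was -0.0131 against a simulated mean of -0.00726, a difference of -0.00584, or -4.05% of the variance of the dexamethasone changes (0.144). The observed covariance lay within the simulated range of -0.0256 to 0.00673, so this difference was not told apart from none. When simulated changes were added to 200 genes in independent noise, 40.3% of those changed 1.2-fold were called in this comparison. The shares were 83.6% for 1.5-fold and 100% for 2-fold changes, and need not hold for another number of changed genes.

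The comparison of dexamethasone plus THSG with vehicle asked which changes were present when both compounds were given. The genes with the largest rise included those of dexamethasone alone, with Ctla2a at 888 ± 63 FPKM (log2 fold change 7.10, n = 3), Mt2 at 1922 ± 90 (3.97), Fkbp5 at 98.6 ± 2.7 (3.89), Selenop at 451 ± 12 (3.79) and Pdk4 at 81.2 ± 2.8 (3.44). Il1rn, the interleukin 1 receptor antagonist, rose from 5.77 ± 2.0 to 51.4 ± 3.7 FPKM (3.19, SE 0.235). The atrophy ligase genes Fbxo32 and Trim63 rose by 2.06 and 0.71, and Actc1 by 0.86. G0s2, Igfbp4, Dynap, Timp3 and the matrix gene Edil3 had log2 fold changes of -2.58, -2.54, -2.50, -2.36 and -2.11, and Top2a one of -1.89. Of 10716 genes, 3120 (29.1%) changed in the limma test, 1294 higher and 1826 lower, with changes of at least 2-fold in 134 and 170. Of the called genes 41.5% were higher as deposited, 42.2% with libraries scaled to equal sums, 50.9% with median-ratio scaling and 49.8% with quantile normalization.

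By list, 15 of 28 passed camera against vehicle, 8 higher and 7 lower, and 7 kept their call with an estimated correlation. Glucocorticoid response genes were higher in 20 of 24 cases and lower in 1, also adjusted over the list alone (adjusted p = 0.00106 with an estimated correlation). The atrophy list had 12 higher and 0 lower of 23, also adjusted over the list alone (adjusted p = 0.0212 with an estimated correlation). Cholesterol synthesis was lower in 19 of 20 genes and the cell cycle in 18 of 20, with the same numbers adjusted over the list alone (adjusted p = 0.0352 and 0.0212 with an estimated correlation). Sarcomere genes were higher in 28 of 40 cases, and in 30 adjusted over the list alone (camera adjusted p = 7.3e-15, but adjusted p = 0.0713 with an estimated correlation).

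Of the genes called against vehicle, 2680 were called both with and without THSG, all in the same direction, 1112 higher and 1568 lower. Independent lists of these sizes would share 164 higher and 382 lower genes. Simulations in which neither treatment had an effect gave a mean overlap of 0.02 genes (at most 2), but they make few calls and do not show what shared vehicle libraries add to lists of this size. Across genes the changes correlated with r = 0.943 (mean 0.485 and range -0.386 to 0.9365 without effects), and had a covariance of 0.146 against a simulated mean of 0.00737. Simulations of a THSG group that did not differ from dexamethasone, built on the measured means, gave higher values than observed, with overlaps from 2723 to 4361 genes and covariances from 0.1525 to 0.1835. The measured means carry noise that enlarges the simulated changes, and with changes reduced by that noise variance the observed values lay in the lower part of the range, with overlaps from 2503 to 4317 genes (96 of 100 at or above 2680) and covariances from 0.1387 to 0.1697 (80 of 100 at or above the observed). The 3 vehicle libraries could not be split into independent sets of replicates, so part of the overlap may come from them. A further 921 genes passed only without THSG and 440 only with it. The direct test of the difference, the comparison of the THSG and dexamethasone groups, called 0 genes.

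**Figure D3:**
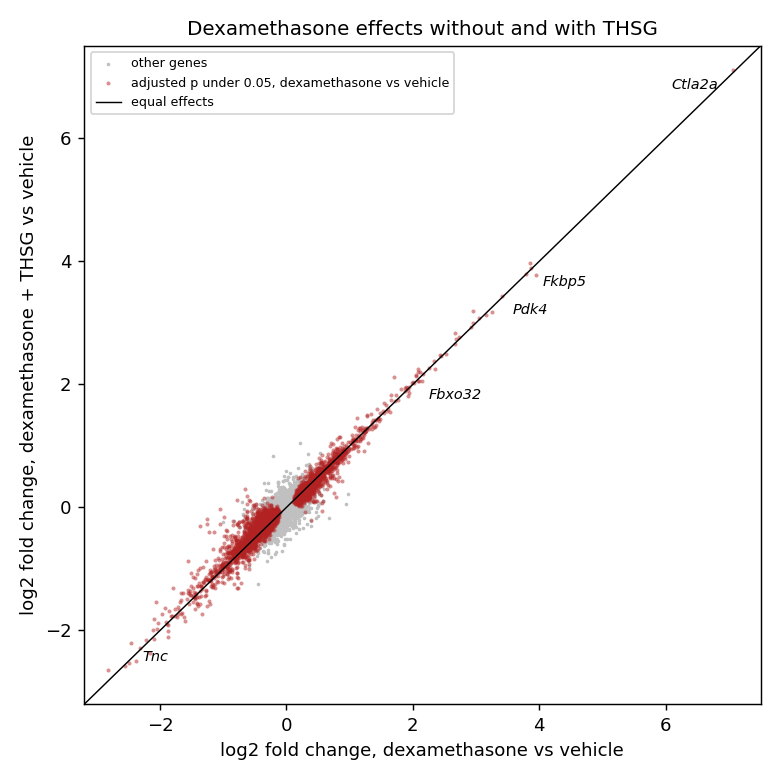
Log2 fold changes against vehicle of 10716 genes (points), with dexamethasone alone on the horizontal axis and with dexamethasone plus THSG on the vertical axis; red points are the 3601 genes past an adjusted p of 0.05 for dexamethasone alone, and the line marks equal changes. Points follow the line, with Ctla2a at 7.06 and 7.10 and Fbxo32 at 2.08 and 2.06.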

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

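The scaling, pseudocount, filter, trend and GC alternatives were chosen after seeing the data; the fit on the compared groups, the replicate block, the leave-one-out settings and the list tests were fixed before. The planned count tests and count normalizations were not run, since they need counts; a filter at 1 CPM could not be set on FPKM, and no filter equals the values reported. Between 2956 and 3747 genes changed with dexamethasone and between 2559 and 3406 with dexamethasone plus THSG against vehicle, the lowest without vehicle replicate 1 and without dexamethasone plus THSG replicate 2. After the GC and length correction 3747 genes changed with dexamethasone, of which 3225 were among the 3601 called as deposited. For THSG against dexamethasone the count was 0 to 1, and so was the count of genes with opposite calls. The 1 gene was Rps2-ps10, a ribosomal protein pseudogene, with the replicate block (log2 fold change 0.47, adjusted p = 0.0215) and with the block and the GC and length correction (0.43, 0.00622), and Cks2, a cell cycle gene, without dexamethasone replicate 3 (0.86, 0.0383); both names were chosen after their values were seen. Replicate numbers gave no clear pairing. Residuals of libraries with the same number correlated between -0.09 and 0.11, and those with different numbers between -0.12 and 0.11. Of the 9 libraries, 5 matched best with their own number. With 3 libraries per group a weak pairing cannot be excluded, so the block stands as an alternative only. Of 2433 alternative values for 122 gene results, 2400 kept direction and side of the threshold, 2 were weaker (Myod1 with dexamethasone, -0.095 with the GC correction, with or without the block), 3 passed where the reported value did not (Foxo1 with dexamethasone, -0.198 without the trend and -0.273 with the GC correction) and 28 reversed. All reversals were of differences that passed in no setting. Myog with dexamethasone was 0.048 with median-ratio scaling, 0.02 with equal sums, 0.041 with quantile normalization, 0.058 with the GC correction with or without the block, and -0.02 to 0.023 leaving out libraries. For THSG against dexamethasone, Fkbp5 was -0.001, -0.004 and -0.004 under those scalings (-0.007 to 0.032 leaving out libraries). With the GC correction, with or without the block, Fbxo32 was 0.01 (-0.046 to 0.000), Trim63 -0.007 (-0.054 to 0.07), Myod1 -0.033, and Myog -0.023 (-0.017 to 0.044), with Myog at -0.043 under quantile normalization; Nr3c1 ranged from -0.021 to 0.122 leaving out libraries. The cause was not tested. Of 770 alternative values for 35 list calls, 727 kept the call and 43 lost it, 0 in the other direction. Unknown depth leaves the counting error of low values open.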

Other observations

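The tests of scaling, of shared libraries and of cell composition, the splits of the libraries and the symbol families were chosen only after the results they bear on were seen. Dexamethasone also changed genes of lists that camera did not call. Of 24 growth and myostatin signalling genes, 8 were higher and 7 lower (9 and 7 adjusted over the list alone, camera adjusted p = 0.267, with a median of 0.06 and a mean of -0.07): Pik3r1, a regulatory subunit of PI3 kinase, rose from 14.3 ± 0.36 to 25.2 ± 1.8 FPKM, while Igfbp5 fell from 422 ± 9.2 to 284 ± 7.6. In the redox and NRF2 list 5 of 24 were higher and 11 lower (6 and 11 adjusted over the list alone, 0.691; 3 and 9 without dexamethasone replicate 3), with a rise of the glutathione enzymes Gpx3 (33.3 ± 2.9 to 128 ± 5.4 FPKM) and Gstm1 (25.6 ± 1.9 to 62.3 ± 2.3) and a fall of G6pdx (15.1 ± 0.081 to 10.1 ± 0.24); the list's median was -0.12 while fry's direction was up (0.981). Glycolysis and glucose uptake had 3 of 20 higher and 11 lower, also adjusted over the list alone (0.0584; 5 higher after the GC and length correction or with quantile normalization), among them the lactate transporter gene Slc16a3 (log2 fold change -1.09), Pgam1 (-0.62) and Eno1 (-0.53). In cell death and p53, 7 of 20 were higher and 5 lower, also adjusted over the list alone (0.111), and 3 lower with median-ratio or quantile scaling, with Trp53inp1 at 9.07 ± 0.13 and 40.6 ± 1.8 FPKM, the survival gene Bcl2l1 at 30.5 ± 0.48 and 54.3 ± 0.75, and Casp8 at 8.71 ± 0.16 and 5.50 ± 0.062. Of 27 autophagy and lysosome genes, 5 were higher and 3 lower (6 and 4 adjusted over the list alone, 0.214), and 8 higher with median-ratio or quantile scaling, with Atg12 rising from 12.8 ± 0.19 to 29.7 ± 0.72 FPKM; the median of -0.006 and camera's upward direction differed in sign, and the median was 0.04 with median-ratio scaling.

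At the neuromuscular junction, 5 of 16 genes were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.178), and 8 higher after the GC and length correction, with the kinase gene Musk up by 0.46. Of 6 fibroblast markers 3 were higher and 2 lower, also adjusted over the list alone (0.214), and the receptor genes went apart, Pdgfra up by 1.31 and Pdgfrb at -0.89. Among adipocyte markers, not tested as a list, the transcription factor gene Cebpa rose from 6.25 ± 1.1 to 26.5 ± 0.98 FPKM and Pparg was not called (2.33 ± 0.37 and 2.74 ± 0.44, adjusted p = 0.308). Of the chaperones, also not tested as a list, Cryab rose by 0.36 and Dnajb1 was at -0.55. The circadian clock list had 2 of 15 higher and 4 lower (4 and 5 adjusted over the list alone, 0.953), and 4 higher with median-ratio scaling, with Per1 up by 1.52 and Per3 at -0.999; the median was -0.10 while fry pointed up (0.685). Immediate early genes were 7 higher and 7 lower of 18, also adjusted over the list alone (0.953), with Zfp36 up by 0.79 and Ier3 at -1.28. Of 6 aryl hydrocarbon receptor targets 1 was higher and 3 lower (3 and 3 adjusted over the list alone, 0.953), and 3 higher with median-ratio or quantile scaling, Ugt1a6a, which shares exons with its gene family, up by 0.98 and Aldh3a1 at -1.03; the median of -0.23 and camera's upward direction differed in sign. In mitochondrial biogenesis and dynamics 1 of 15 was higher and 2 lower (1 and 1 adjusted over the list alone, 0.774), with Sirt1 up by 0.50 and the uncoupling protein gene Ucp2 at -0.67, and camera pointed up while fry pointed down (0.0447). Oxidative phosphorylation had 2 of 40 higher and 7 lower (1 and 1 adjusted over the list alone, 0.425), with Cox8b at -0.45; 3 were lower with median-ratio scaling and 1 without dexamethasone replicate 3. Of 121 families of genes with shared symbol letters, 4 passed camera with dexamethasone: collagen genes (Col, 12 of 18 lower), ribosomal protein genes (Rpl, 19 of 48 lower), myosin heavy chain genes (Myh, 6 of 10 higher) and genes of the secretory pathway (Sec, 12 of 24 lower), with adjusted p = 0.00437, 0.00437, 0.0292 and 0.0449, but adjusted p = 0.999 for each with an estimated correlation. With THSG added to dexamethasone, Rpl and Rps passed upward (0.003 and 0.0342, with 0 genes called), but adjusted p = 0.961 for each with an estimated correlation.

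With dexamethasone, the cell cycle list fell (median log2 fold change -1.18) and 27 of 40 sarcomere genes were higher (median 0.26, list adjusted p = 0.0818 with an estimated correlation), which a lower share of undifferentiated cells beside the myotubes could give. Such a loss would lower the markers of these cells together, but 25% of the 12 called members of the list of undifferentiated myoblasts and reserve cells were higher, 3 genes, with Myf5 at 7.74 ± 0.52 and 16.2 ± 1.5 FPKM, against 9 lower, among them Notch3 (31 ± 1.8 and 10.7 ± 0.54) and Cd34 (25.8 ± 1.8 and 11.4 ± 0.61; list camera adjusted p = 0.0672, same counts adjusted over the list alone; its member Vcam1 is also in the inflammatory list). The limits for this share were set after the values were seen, and Myf5 could also have changed within such cells. The share therefore does not decide whether a loss of such cells was the source. A trend over GC content and length is argued against, since the cell cycle median was -1.17 after its removal. Whether expression changed within the myotubes stays open and was not tested.

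With THSG added to dexamethasone, 69.6% of the genes at an unadjusted p under 0.05 were higher. Removing the GC and length trend left 72.4%. That correction keeps the mean of each library, so it could not remove an offset between libraries and does not decide the part of GC content. The median log2 fold change was 0.016 before it and 0.015 after. Leaving out dexamethasone replicate 3 left 71.6%, which argues against that library as the whole cause. With libraries scaled to equal sums the share was 57.2% and with median-ratio scaling 58.3%, which leaves the scaling between libraries open as a partial source, while the 52.4% under quantile normalization decides nothing because that method makes the distributions equal. After the GC and length correction the real grouping gave 686 such genes and the highest of the other splits 651. That met the outcome set for an effect of THSG before this count was made. The splits and the correction had, however, been chosen after the data were seen. The verdict also used a stricter margin that the prediction had not stated. Without the correction the real grouping gave 777 against 849. Whether THSG itself contributed stays open, because the margin was small and was absent without the correction.

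Of the 3601 genes changed by dexamethasone, 68.8% (2478) had a smaller change against vehicle when THSG was given, and the median change was 89.9% of that without THSG, within the 80.6% to 104.5% (mean 96.1%) of simulated groups that did not differ from dexamethasone. Selecting genes on the shared dexamethasone libraries gives such a shrinkage by itself: in these simulations the share had a mean of 57.9% and reached up to 74.3%, with 7 of 100 as high as observed (6 of 100 with changes reduced by their noise variance), so the sharing could account for it, although few simulations went so far. After the GC and length correction the share was 65.3%, just inside the highest simulated value of 65.8% (2 of 100 as high), which leaves the contribution of that trend open. Leaving out dexamethasone replicate 3 gave 68.4%. That lay within the 3 percentage points set beforehand as the outcome against that library as the cause, so the share did not rest on it alone. Simulated groups without it reached 74.7% (mean 59.1%, 5 of 100 as high). Whether that library added a part therefore stays open. A slight weakening of the dexamethasone response by THSG remains a hypothesis that these libraries do not settle.

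The 3 libraries of each of 2 groups can be split in only 10 ways, too few for a share under 0.05. For dexamethasone against vehicle 1 of 10 splits, the real one, gave as many as 3601 genes, and the highest other gave 0. For dexamethasone plus THSG against vehicle the real split gave 3120, again 1 of 10, and the highest other 0. For THSG against dexamethasone the real split gave 0, which all 10 reached, and the highest other 1.

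A further pattern was tested and not decided: mitochondrially encoded genes had a median log2 fold change of 0.20 with dexamethasone, 0.14 without dexamethasone replicate 3 and 0.12 after the GC and length correction. The scaling moved this median as well, to 0.25 with median-ratio scaling, 0.22 with equal sums and 0.09 with quantile normalization.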
